A study of Arabidopsis thaliana with 12 samples.

How the data were processed

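Whole-genome expression arrays (Affymetrix ATH1) were read from leaves of soil-grown Arabidopsis thaliana, accession Col-0. The 12 arrays fall into 4 groups of 3: leaf 13 of unwounded plants, leaf 13 of plants whose leaf 8 had been wounded, leaf 8 fitted with a platinum wire without current, and leaf 8 after current. The labels name each array's group and replicate number. Plants were 5 weeks old and grew with 10 h of light a day at 100 µE, at 22 °C by day and 18 °C by night and 70% humidity, per the labels. Per the labels' protocols, 300 ng of total RNA was amplified and 12.5 µg of labelled cRNA was made for hybridisation. The labels do not say whether replicates were separate plants or pools, so p-values measure only the spread between these samples, which may be technical. The labels name wounding and current injection as experiments with controls of their own, and do not say whether both were done together.

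The deposited values are RMA expression values made with Affymetrix Power Tools, per the submitters' processing notes, with versions not given in the sources used here. RMA values are on the log2 scale by construction, and the deposited values, from 1.46 to 13.3, fit that scale, although no label states the log base. RMA subtracts background, equalises the distribution of intensities between arrays and summarises the probes of a probe set. A change in total RNA shared by most genes would therefore be removed, and levels near the lower end carry little signal over background, so that folds of genes rising from there are understated. The values were used as deposited, with no further normalization, pseudocount or filter. For arrays, their number, 3 per group, limits the precision, and the smallest p of an exact test of 3 against 3 arrays is 0.1.

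Of 22810 probe sets, 64 were controls. Genes were named from the probe-gene table given for the platform, in which 13513 probe sets had 1 gene and 503 had several; 8730 others were not named there. Probe sets with several genes or none were left out of the gene tests. The 146 genes with more than 1 probe set were given their mean, which left 13356 genes. Of these, 13286 matched the reference gene table by identifier and took its current symbol, and 70 kept the older name. The naming is uneven: 14.6% of the protein-coding genes that carry a symbol in the reference were tested, against 63.1% of those known by locus identifier alone. Many well-known genes are therefore not analysed here, and counts of genes describe the named part of the array.

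Groups were compared with limma (version 3.58.1, R version 4.3.3), fitting 1 mean per group over all 12 arrays so that all groups share 1 variance per gene, with empirical Bayes moderation (8 residual and 6.31 prior degrees of freedom). All tests were two-sided, with Benjamini-Hochberg adjustment over the 13356 genes and a threshold of 0.05. The contrasts were wounded against unwounded for leaf 13, current against no current for leaf 8, the difference of these responses, and the no-current against the unwounded leaves. The last is a description only, because leaf position, wire and experiment differ together. Overlap of calls was set against the number expected of independent lists and tested with Fisher's exact test across genes, and fold changes were correlated across genes. Genes are not independent replicates in either. The wound and current comparisons share no arrays.

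A total of 21 gene lists were fixed from textbook knowledge before the data were examined, as were the tests, the rule for naming genes and most alternatives. The lists were JAZ repressors, jasmonate synthesis, turnover, signalling and defence outputs, rapid stress transcription factors, touch and calcium, glucosinolate synthesis, salicylic acid, abscisic acid and dehydration, ethylene, auxin response, heat shock, the circadian clock, photosynthesis and electrical signalling candidates. Markers of guard cells, vascular tissue, trichomes, dividing cells and senescence completed them. Each list with at least 3 measured members, 10 in all, was tested with camera in limma (preset correlation 0.01) against the other genes, with adjustment over the 10 lists within a comparison. An estimated correlation was run beside it, as was the fry test, which sets a list against no change and not against the other genes. Counts of members past the threshold are given over all genes and adjusted over the list alone. WRKY53 is in both the rapid stress and the senescence list.

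The genes named for wounding and for current were the 10 largest rises and 5 largest falls among genes past the threshold whose treated arrays all lay beyond the control arrays. From each list, up to 4 members past the threshold and up to 2 others were added, by size of change. GLR3.3 and GLR3.6 were always named. JAZ10, LOX2, VSP2 and MYC2 were to be named as well, but were not analysed here for lack of a named probe set. For the difference of the responses and for the control leaves, the 5 largest changes each way were named.

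The fit was tested on simulated values with 200 changed genes among the 13356. Noise was normal, independent between genes, and had the fit's own variance for each gene in all groups. The shares therefore hold for such values, and not for genes that vary together or groups of unequal spread. For wounding the fit recovered 50.7% of changes of 0.5 log2, 98.5% of changes of 1 and 100% of changes of 2, and 11 of its 177 calls were false. For current the shares were 56.7%, 100% and 100%, with 10 false of 181 calls. For the difference they were 19.4%, 95.5% and 100%, with 12 false of 155, and for the control leaves 59.7%, 100% and 100%, with 17 false of 190.

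Alternatives were each comparison fitted alone, the replicate number as a block, quantile normalization of the deposited values, centring each array on its median, leaving out the dimmest 25% or 50% of the genes, the brightest probe set in place of the mean, every probe set, robust empirical Bayes with an intensity trend, array weights, an adjusted p under 0.01, at least 2-fold change, an estimated correlation, fry, and leaving out each array in turn. Families of genes that share a symbol stem, and the plastid-encoded genes, were tested after the data were seen, 38 sets in all.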

Results

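Leaf transcripts were measured on 12 arrays from 5-week-old Arabidopsis plants, 3 arrays in each of 4 groups. In one experiment the apical 40% of leaf 8 was wounded with forceps and the undamaged leaf 13 was harvested 1 h later, with leaf 13 of unwounded plants as the control. In the other, a current of 40 µA was passed into the petiole of leaf 8 for 10 s through a platinum wire and the blade of that leaf was harvested 1 h later, with wired leaves that received no current as the control. Values are log2 RMA expression values, means are given ± SD with n = 3 arrays, and changes are log2 fold changes with limma's standard error (SE). Arrays of 1 group correlated with r from 0.991 to 0.996, and the lowest r of any pair was 0.948. The 3 arrays per group limit the precision, and a change of a typical gene had an SE of 0.113.

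The first comparison asks what an undamaged leaf expresses after another leaf is wounded. Genes of jasmonate metabolism were among those that rose most. AT5G05600, listed as the jasmonate oxidase JOX2, rose from 4.19 ± 0.57 to 9.99 ± 0.13, a change of 5.80 (SE 0.24, n = 3, limma adjusted p = 1.35e-09) or 55.8-fold. AT2G38240, listed as JOX4, rose by 5.09 (SE 0.32), JRG21, listed as JOX3, by 3.93 (SE 0.39) and JMT, which methylates jasmonic acid, by 3.13 (SE 0.15). With AT3G11180, listed as JOX1, at 0.36 (SE 0.09), named after its value was seen, 5 of the 5 measured members of the jasmonate turnover list rose, of 11 fixed, and 5 adjusted over the list alone. The list stood above the other genes (camera adjusted p = 6.63e-12, and adjusted p = 0.0201 with an estimated correlation).

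In jasmonate synthesis, the 1 measured enzyme of 16, OPCL1, a coenzyme A ligase of the peroxisomal steps, rose by 3.64 (SE 0.19), from 7.71 ± 0.14 to 11.35 ± 0.32. Of 3 measured members of the jasmonate signalling list, of 10, the transcription factors ORA47 and MYC3 rose by 3.35 (SE 0.23) and 0.83 (SE 0.18), 2 also adjusted over the list alone, while MYC4 was at -0.28 (SE 0.22). That list passed (camera adjusted p = 0.00808), but not with an estimated correlation (adjusted p = 0.134 with an estimated correlation). Of the 3 measured defence outputs, of 11, limma called 0, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The defensins PDF1.2 and PDF1.2b were at -1.01 (SE 0.74) and -0.98 (SE 0.62), with an SD of 2.15 and 1.84 among the unwounded arrays, and the list did not pass (camera adjusted p = 0.639). Without unwounded replicate 1 both turned direction, to 0.22 and 0.06.

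**Figure D1:**
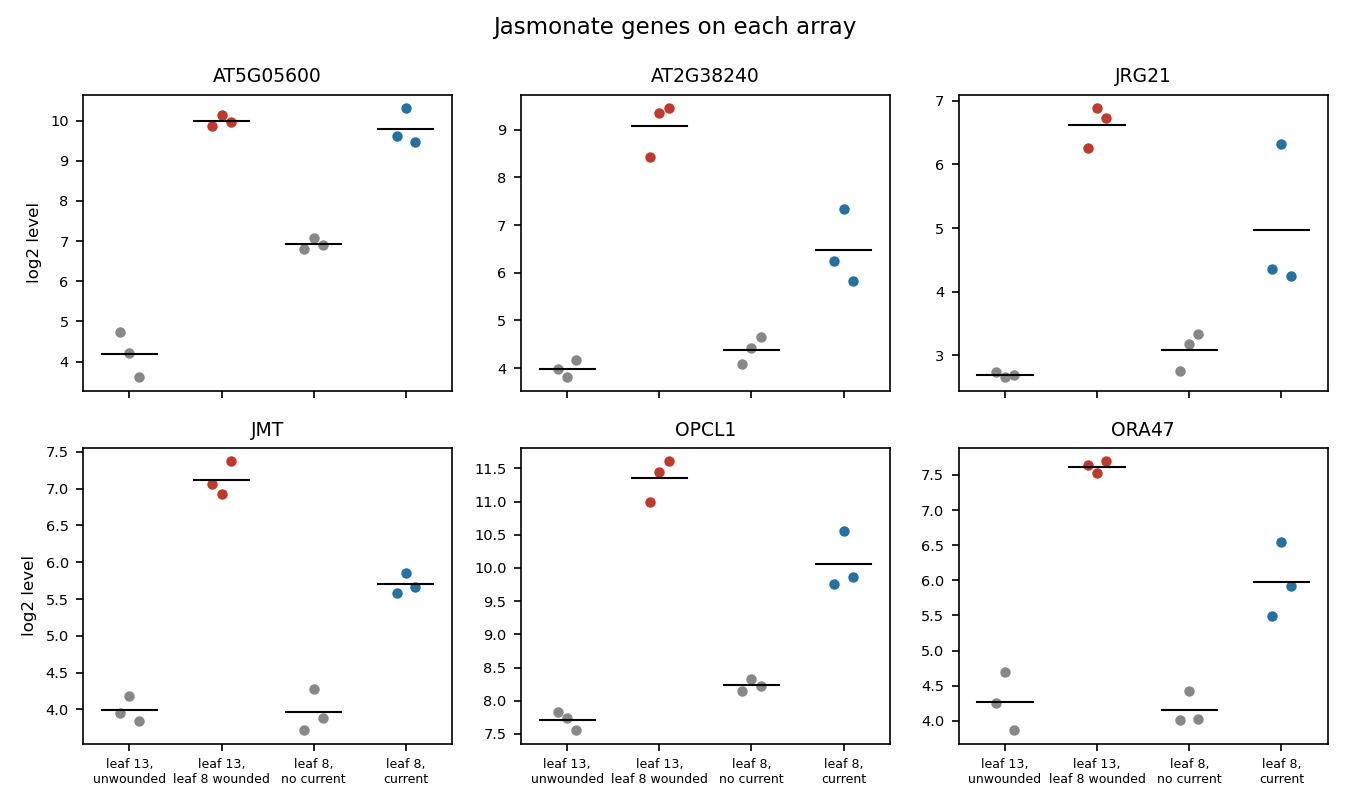
Each point is the log2 RMA level of 1 gene on 1 array, for 6 genes of jasmonate turnover, synthesis and signalling, in the 4 groups of 3 arrays, and black lines are group means. AT5G05600 lay at 4.19 in unwounded leaf 13 and at 6.93 in leaf 8 without current, and reached 9.99 after wounding and 9.80 after current.

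Of 3 measured rapid stress regulators 1 rose in the distal leaf. STZ, the zinc finger repressor also known as ZAT10, rose by 3.83 (SE 0.26), while WRKY6 and WRKY53 were at 0.45 (SE 0.16) and 0.41 (SE 0.15) and did not pass. The rapid stress list, with 3 of 31 members measured, had 1 gene called and 3 higher adjusted over the list alone (camera adjusted p = 9.79e-04, and adjusted p = 0.0321 with an estimated correlation). Without wounded replicate 2, WRKY53 passed (limma adjusted p = 0.0211) and WRKY6 was at 0.25, and without wounded replicate 3 WRKY53 was at 0.22. Of 8 measured touch and calcium genes, of 13, 3 calmodulin-like genes rose: CML38 by 3.11 (SE 0.30), AT1G76640 by 2.8 (SE 0.16) and AT3G01830 by 1.96 (SE 0.35). CML42 fell by 0.53 (SE 0.14), and CML41 and CML43 were at 0.21 and -0.11 (SE 0.13 and 0.10). The counts were the same adjusted over the list alone, 3 higher and 1 lower (camera adjusted p = 0.00808, but adjusted p = 0.134 with an estimated correlation). The call of CML42 ended without unwounded replicate 1 or wounded replicate 1 or 2 (limma adjusted p = 0.0825, 0.0536 and 0.0751).

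Genes of the abscisic acid and dehydration list rose together by smaller amounts. That list holds genes induced by abscisic acid, drought or cold, and its members are called dehydration genes only for short. The measured members cannot tell these stimuli apart. All 4 measured members of that list, of 24, rose: the dehydrins LTI30 by 2.18 (SE 0.20) and COR47 by 0.84 (SE 0.10), and the chloroplast proteins COR15A by 0.88 (SE 0.11) and COR15B by 0.64 (SE 0.17). The count was 4 adjusted over the list alone and the list passed (camera adjusted p = 1.42e-06), but not with an estimated correlation (adjusted p = 0.0764 with an estimated correlation). COR15B lost its call without unwounded replicate 2 or wounded replicate 3 (limma adjusted p = 0.0734 and 0.101). UGT74B1, a glucosyltransferase of glucosinolate synthesis, rose by 1.29 (SE 0.13), and BCAT4, at the start of that pathway's side-chain branch, was at 0.08 (SE 0.17), so 1 of 2 measured members, of 21, was called, and 1 adjusted over the list alone.

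Among electrical signalling candidates, the glutamate receptor-like channel gene GLR3.3 rose by 0.96 (SE 0.14, limma adjusted p = 2.03e-04). GLR3.6 fell by 0.55 (SE 0.14, limma adjusted p = 0.0147) and GLR3.5 fell by 0.31 (SE 0.09, limma adjusted p = 0.0371). GLR2.7 and ATGLR1.2 were at 0.23 (SE 0.18) and 0.09 (SE 0.11). Of 8 measured members, of 24, 1 was higher and 2 lower, likewise adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.768). The call of GLR3.6 ended without unwounded replicate 2 or 3 or wounded replicate 1 (limma adjusted p = 0.0609, 0.0743 and 0.0658). That of GLR3.5 ended when the comparison was fitted alone, with quantile normalization, median centring or a robust trend (limma adjusted p = 0.0660, 0.0781, 0.0933 and 0.0686). It also ended without unwounded replicate 2 or 3 or any 1 wounded replicate (limma adjusted p = 0.174, 0.0628, 0.0918, 0.0508 and 0.122).

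The auxin-inducible gene IAA29, which encodes an Aux/IAA repressor, fell by 2.68 (SE 0.33), from 6.67 ± 0.20 to 3.99 ± 0.61. GH3.3 and WES1, listed as GH3.5, both enzymes that conjugate auxin, were at 0.76 (SE 0.31) and -0.67 (SE 0.25). Of 4 measured auxin genes, of 11, 1 was called lower, and 1 was higher and 2 lower adjusted over the list alone (camera adjusted p = 0.356). Limma called 0 of 3 measured heat shock genes, of 20, and 0 adjusted over the list alone, with 1 higher at an unadjusted p under 0.05. AT1G53540 was at 0.29 (SE 0.11) and ATHSP22.0 at -0.09 (SE 0.12), and the list had a median of -0.08 and a mean of 0.04 (camera adjusted p = 0.668). It also called 0 of 3 photosynthesis genes, of 20, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The antenna genes LHCB4.2 and LHCB4.1 were at -0.13 (SE 0.09) and 0.12 (SE 0.08), and camera ranked the list upwards (camera adjusted p = 0.900) although its median was -0.04 and its mean -0.02.

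Lists with under 3 measured members were not tested as lists. SWEET11, a sucrose transporter of the phloem and the 1 measured vascular marker of 9, fell by 0.48 (SE 0.15, limma adjusted p = 0.0477), 1 lower also adjusted over the list alone. Its call was lost with median centring (limma adjusted p = 0.0871) and without any 1 of the 6 arrays (0.0600 to 0.155). The guard cell genes FMA, listed as FAMA, and AT1G22690, listed as GC1, 2 of 6, were at -0.32 (SE 0.16) and -0.32 (SE 0.15), and limma called 0 of them, with 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. The ethylene regulator EIN3 (1 of 15) was at 0.04 (SE 0.11), the clock gene GI (1 of 19) at 0.06 (SE 0.17), the trichome regulator TRY (1 of 4) at 0.08 (SE 0.21) and the senescence marker SAG29 at 0.07 (SE 0.15). None of these 4 passed in limma, with 0 at an unadjusted p under 0.05. Of 2 measured senescence genes, of 5, 0 were called over all genes and 1, WRKY53, was higher adjusted over the list alone. No member of the JAZ, salicylic acid or dividing cell lists, with 12, 14 and 6 genes, was measured here.

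Outside the lists, the largest rises after distal wounding belonged to AT4G10390 at 5.35 (SE 0.28), AT2G30830 at 4.92 (SE 0.27), AT5G56980 at 4.78 (SE 0.20), AT3G51450 at 4.77 (SE 0.32) and AT4G17470 at 4.66 (SE 0.32). AT2G22880 at 4.61 (SE 0.37), AT4G36010 at 4.60 (SE 0.31) and 4CL8, a 4-coumarate:CoA ligase-like gene, at 4.54 (SE 0.19) followed. The largest falls were those of AT5G07580 at -2.87 (SE 0.28), IAA29, AT5G61590 at -2.66 (SE 0.27), AT5G11070 at -2.51 (SE 0.25) and AT3G19850 at -2.45 (SE 0.18). AT5G61590 carries the synonym DEWAX in the reference and encodes a repressor of wax synthesis. In all, 1900 of 13356 genes passed in limma, 776 higher and 1124 lower. Of these, 336 were at least 2-fold higher and 189 at least 2-fold lower. The arrays of both groups did not overlap for 30.3% of all genes, where chance gives 10%.

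The second comparison asks what a leaf expresses 1 h after current enters its petiole. Jasmonate turnover genes rose here too. AT5G05600 rose from 6.93 ± 0.13 to 9.80 ± 0.45, by 2.87 (SE 0.24, n = 3, limma adjusted p = 1.27e-05) or 7.31-fold. AT2G38240 rose by 2.09 (SE 0.32), JRG21 by 1.89 (SE 0.39) and JMT by 1.74 (SE 0.15), while AT3G11180 was at 0.20 (SE 0.09). So 4 of 5 measured members rose, and 5 adjusted over the list alone (camera adjusted p = 1.83e-11, and adjusted p = 0.0226 with an estimated correlation). JRG21 lost its call when the comparison was fitted alone or with a robust trend (limma adjusted p = 0.0911 and 0.0760), and without no-current replicate 1 (limma adjusted p = 0.0614).

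OPCL1 rose by 1.83 (SE 0.19), from 8.23 ± 0.09 to 10.06, and was the 1 measured synthesis gene. ORA47 rose by 1.83 (SE 0.23), while MYC3 and MYC4 were at 0.30 (SE 0.18) and 0.07 (SE 0.22), so 1 of 3 signalling genes was called, and 1 adjusted over the list alone. The signalling list passed (camera adjusted p = 0.0166), but not with an estimated correlation (adjusted p = 0.230 with an estimated correlation). It also missed the threshold without no-current replicate 3 (camera adjusted p = 0.0507) or current replicate 3 (camera adjusted p = 0.0892). MYC4 turned to -0.04 with array weights and to -0.22 at the lowest without 1 array. PDF1.2 and PDF1.2b were at 0.83 (SE 0.74) and 0.66 (SE 0.62), and limma called 0 of 3 defence outputs, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.440). That list passed when the comparison was fitted alone (camera adjusted p = 0.0274).

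STZ rose by 1.11 (SE 0.26, limma adjusted p = 0.0278) and CML38 by 1.35 (SE 0.30, limma adjusted p = 0.0169). WRKY53 and WRKY6 were at 0.12 (SE 0.15) and 0.09 (SE 0.16), and the calmodulin-like genes AT3G01830 and AT1G76640 at 0.64 (SE 0.35) and 0.47 (SE 0.16). Of 3 rapid stress genes 1 was called, and 1 adjusted over the list alone (camera adjusted p = 0.0942). Of 8 touch and calcium genes 1 was called, and 2 adjusted over the list alone (camera adjusted p = 0.123, or 0.0454 without current replicate 1 and 0.473 without current replicate 2). AT3G01830 was at 1.02 and 0.18 without these arrays. The calls of STZ and CML38 ended with a robust trend (limma adjusted p = 0.0833 for STZ and 0.0595 for CML38), and that of CML38 also when the comparison was fitted alone (0.0602). STZ was not called without any 1 no-current replicate (limma adjusted p = 0.0890, 0.0612 and 0.0920) or without current replicate 2 or 3 (limma adjusted p = 0.153 and 0.0633), and CML38 was not without no-current replicate 2 or 3 or current replicate 2 (limma adjusted p = 0.0713, 0.0768 and 0.0864).

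Dehydration genes had no call in the current comparison. Limma called 0 of 4, with 3 lower at an unadjusted p under 0.05 and 3 lower adjusted over the list alone. COR15B was at -0.57 (SE 0.17), COR47 at -0.38 (SE 0.10) and the list at a median of -0.35 (camera adjusted p = 0.0727). COR15B and COR47 passed without current replicate 1 (limma adjusted p = 0.0163 and 0.0469), and COR47 also with a robust trend (0.0326) or without the dimmest 50% of genes (0.0429). The list was past the threshold with a robust trend (camera adjusted p = 0.0464) and without current replicate 1 or 2 (camera adjusted p = 0.0214 and 0.0184), and far from it without current replicate 3 (camera adjusted p = 0.407), where COR15B was at -0.34. UGT74B1 rose by 0.89 (SE 0.13) and BCAT4 was at 0.31 (SE 0.17), 1 of 2 called and 1 adjusted over the list alone.

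The glutamate receptor-like genes GLR3.3, GLR1.4 and GLR3.6 were at 0.43 (SE 0.14), -0.37 (SE 0.19) and -0.31 (SE 0.14). Limma called 0 of 8 electrical signalling candidates, with 4 at an unadjusted p under 0.05, 2 in each direction, and 0 adjusted over the list alone (camera adjusted p = 0.815). Without current replicate 1, GLR3.3 passed (limma adjusted p = 0.0200). WES1 and IAA29 were at -0.81 (SE 0.25) and -0.57 (SE 0.33), and limma called 0 of 4 auxin genes, with 1 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (camera adjusted p = 0.120). Without no-current replicate 2 WES1 passed (limma adjusted p = 0.00740), as did the auxin list (camera adjusted p = 0.0111). WES1 was at -1.15 without that array and at -0.42 without no-current replicate 1, and IAA29 at -0.26 without the latter.

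Heat shock genes, included as a check for heating by the current, gave no call. ATHSP22.0 and AT5G48570 were at -0.12 (SE 0.12) and -0.12 (SE 0.22), and limma called 0 of 3, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.509). RCA, which activates Rubisco, and LHCB4.1 were at 0.08 (SE 0.08) and 0.01 (SE 0.08), and limma called 0 of 3 photosynthesis genes, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.553). GI was at -0.62 (SE 0.17, limma adjusted p = 0.0549) and TRY at 0.68 (SE 0.21, limma adjusted p = 0.0978), each the 1 measured gene of its list, 1 lower and 1 higher adjusted over the list alone. GI passed with quantile normalization, array weights, a robust trend or without the dimmest 25% or 50% of genes (limma adjusted p = 0.0441, 0.0347, 0.0440, 0.0487 and 0.0443), and without no-current replicate 2 or current replicate 1 (limma adjusted p = 0.0359 and 0.00910), and TRY without the same arrays (limma adjusted p = 0.0271 and 0.0132). SWEET11 was at -0.19 (SE 0.15), EIN3 at -0.02 (SE 0.11), FMA at -0.02 (SE 0.16), AT1G22690 at -0.04 (SE 0.15) and SAG29 at 0.00 (SE 0.15). Limma called 0 of these 5, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone.

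The largest rise after current was that of AT4G10390, by 3.51 (SE 0.28), from 4.21 ± 0.39 to 7.72 ± 0.71. AT3G51450 at 2.77 (SE 0.32), TBL26, of a family that acetylates cell wall polymers, at 2.74 (SE 0.22), AT5G56980 at 2.68 (SE 0.20), AT1G61610 at 2.64 (SE 0.29) and AT2G22880 at 2.63 (SE 0.37) came next. AT2G34930 rose by 2.58 (SE 0.15), AT5G54170 by 2.41 (SE 0.22) and AT2G42760 by 2.41 (SE 0.22). The largest falls were those of AT4G33980 at -2.84 (SE 0.57, limma adjusted p = 0.0102), AT2G38465 at -1.73 (SE 0.28), AT3G15630 at -1.59 (SE 0.25), AT3G28310 at -1.55 (SE 0.29) and AT2G23910 at -1.48 (SE 0.14). AT4G33980 was uneven, at 6.48, 3.48 and 3.15 on the current arrays against a mean of 7.21 ± 0.08 without current. Its call and that of AT3G28310 ended when the comparison was fitted alone (limma adjusted p = 0.0930 and 0.0713), and that of AT4G33980 also with a robust trend (0.0844) or without current replicate 2 (0.0605).

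In all, 529 genes passed in limma after current, 318 higher and 211 lower, with 114 at least 2-fold higher and 21 at least 2-fold lower. The arrays of both groups did not overlap for 16.9% of all genes, where chance gives 10%. The count fell to 291 when the comparison was fitted alone, and to 266, 338 and 329 without current replicate 2, no-current replicate 1 or no-current replicate 3. No-current replicate 1 differed from the other 2 no-current arrays in an RNA measure: probes at the 3' end of actin, GAPDH and ubiquitin exceeded those at the 5' end by a mean of 1.43 there, against 1.05 and 1.12. AT5G26270, named after its values were seen, was at 9.49 on that array against 4.29 and 4.19 on the others. The 211 lower genes became 331 with array weights and 81 when fitted alone, and 324 and 79 without current replicate 1 or 2. Without no-current replicate 1 or 3 they were 96 and 116.

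Set side by side, the responses overlapped. Of the 318 genes higher after current, 284 were also higher after distal wounding, where 18.5 are expected of independent lists, and 97.5% had the same sign. Of the 211 lower after current, 117 were also lower after wounding, where 17.8 are expected (Fisher's exact test across genes, two-sided p = 1.74e-70). The 284 genes had a median rise of 1.57 after wounding and 0.89 after current, and the current change was the smaller in 247 of them. The 117 had medians of -0.83 and -0.61, and the current change was the smaller in 85. In opposite directions 1 gene passed, AT1G72800, named for that reason after its values were seen, at -0.82 after wounding and 0.80 after current. Across the 13356 genes the changes correlated with Pearson r = 0.71 and Spearman rho = 0.43, and across the 2027 genes called in either with r = 0.83 and rho = 0.74; genes are not independent replicates. The same-direction overlap of 401 fell to 261 without no-current replicate 3 and 219 without current replicate 2.

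**Figure D2:**
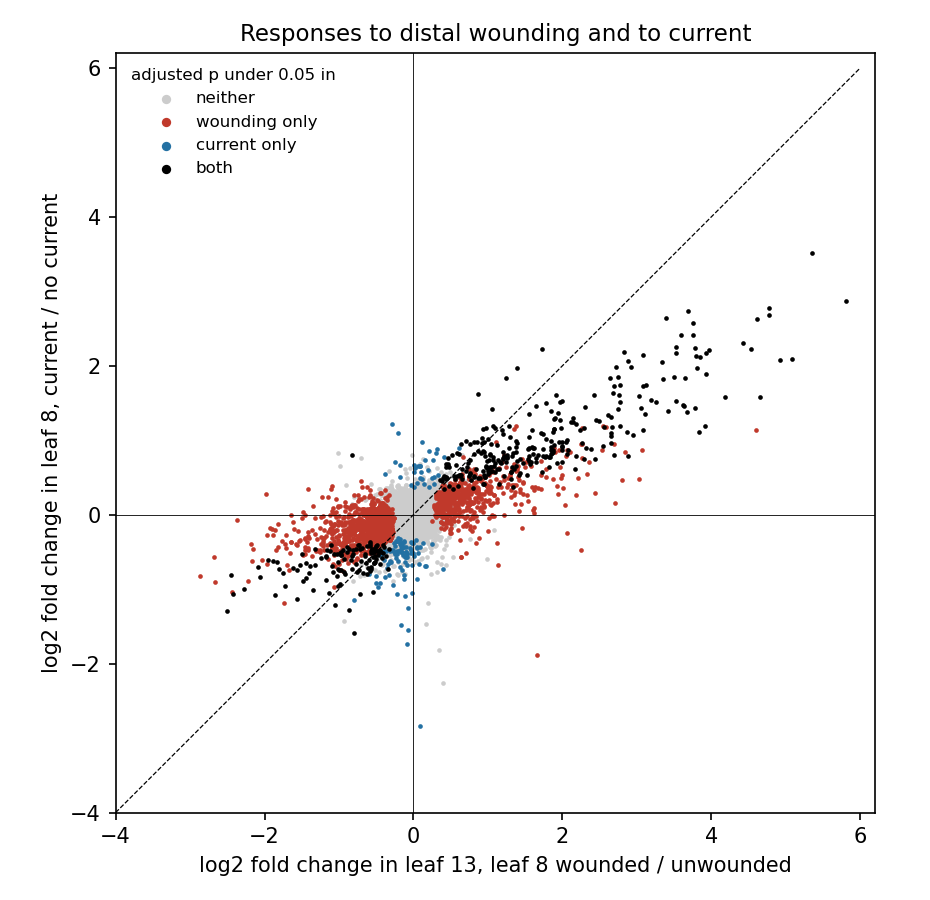
Each point is 1 of 13356 genes, with its log2 fold change in leaf 13 after wounding of leaf 8 on the x axis and in leaf 8 after current on the y axis, coloured by the comparisons in which limma's adjusted p was under 0.05. The dashed line marks equal changes, and 247 of the 284 genes higher in both had the smaller change after current.

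The difference of the responses was tested gene by gene, current minus wounding. Among the genes with the lowest difference were AT5G05600 at -2.93 (SE 0.34) and AT2G38240 at -3.0 (SE 0.45), both of which rose in each comparison. AT5G05600 started at 6.93 without current against 4.19 in unwounded leaves, and reached 9.80 after current and 9.99 after wounding. AT2G38240 started at 4.38 against 3.99, and reached 6.47 and 9.07. AT1G07050 at -3.55 (SE 0.72), AT4G36010 at -3.46 (SE 0.44) and AT4G17470 at -3.08 (SE 0.46) completed the 5. Their levels without current were 7.87, 7.50 and 3.31, against 2.73, 5.53 and 3.16 in unwounded leaves. The highest differences were those of AT5G12050 at 2.3 (SE 0.43), AT5G47610 at 2.26 (SE 0.27), IAA29 at 2.11 (SE 0.46), AT5G07580 at 2.05 (SE 0.40) and AT4G37080 at 1.78 (SE 0.24), and all 5 fell after wounding. In limma 381 genes passed, 178 higher and 203 lower. Of them, 195 were higher after wounding with a smaller or lower current response, 170 were lower after wounding with a higher current response, and 16 were not called after wounding.

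By list, 3 of 5 jasmonate turnover genes had a lower response to current, and 4 adjusted over the list alone (camera adjusted p = 1.99e-09, and adjusted p = 0.0271 with an estimated correlation). So had 4 of 4 dehydration genes, with a median difference of -1.22 (4 adjusted over the list alone, camera adjusted p = 5.12e-11, and adjusted p = 0.0271 with an estimated correlation). In the rapid stress list STZ was lower (1 adjusted over the list alone, camera adjusted p = 0.00251, and adjusted p = 0.0310 with an estimated correlation). STZ also started higher, at 6.07 without current against 3.81 in unwounded leaves, and reached 7.18 after current and 7.64 after wounding. Of the touch and calcium genes 2, CML38 and AT1G76640, were lower, and 3 adjusted over the list alone. That list passed (camera adjusted p = 0.0106), but not with an estimated correlation (adjusted p = 0.170 with an estimated correlation) or without current replicate 1 (camera adjusted p = 0.0819). ORA47 was lower, 1 of 3 signalling genes and 1 adjusted over the list alone (camera adjusted p = 0.0773). The signalling list passed without unwounded replicate 2, wounded replicate 2 or current replicate 2 or 3 (camera adjusted p = 0.0303, 0.0201, 0.0345 and 0.0323).

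The other tested lists did not pass for the difference. Limma called 0 of 8 electrical signalling candidates, with 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.606), so the higher GLR3.3 after wounding was not shown to differ from its value after current (limma adjusted p = 0.247). It called 0 of 3 heat shock genes, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.312). It also called 0 of 3 photosynthesis and 0 of 3 defence genes, with 0 at an unadjusted p under 0.05 in both (camera adjusted p = 0.767 and 0.214), and in all 3 lists 0 adjusted over the list alone. IAA29 alone was called of 4 auxin genes, 1 also adjusted over the list alone, and that list's median was -0.06 against a mean of 0.23 (camera adjusted p = 0.767). With a robust trend IAA29, AT5G07580, AT5G12050 and AT1G07050 lost their calls for the difference (limma adjusted p = 0.120, 0.0629, 0.0623 and 0.115), and IAA29 also without unwounded replicate 2 or 3, wounded replicate 3 or no-current replicate 3 (limma adjusted p = 0.0683, 0.0582, 0.0576 and 0.0519). Leaf position and experiment differ along with the stimulus, and the count of 381 fell to 253, 247, 249, 227 and 241 without unwounded replicate 1 or 2, wounded replicate 2 or 3, or no-current replicate 3.

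The control leaves, wired leaf 8 without current and unwounded leaf 13, also differed from each other, as a description. In wired leaf 8, COR27, a cold-regulated gene, was 5.74 (SE 0.64) above unwounded leaf 13, at 8.35 ± 0.11 against 2.61 ± 0.10. AT1G07050 was 5.14 (SE 0.51), AT4G33980 4.95 (SE 0.57), AT5G47330 4.18 (SE 0.14) and AT1G16850 4.07 (SE 0.24) higher. On the other side stood AT1G11850 at -3.78 (SE 0.18), AT1G33811 at -3.64 (SE 0.14), AT4G02850 at -3.62 (SE 0.19), AT4G29020 at -3.39 (SE 0.24) and AT5G45670 at -3.32 (SE 0.20). The 4 dehydration genes were higher in leaf 8, with a median of 2.28, and 4 adjusted over the list alone (camera adjusted p = 1.26e-06, but adjusted p = 0.101 with an estimated correlation). The 3 rapid stress genes were higher too, with 3 adjusted over the list alone (camera adjusted p = 0.00351, but adjusted p = 0.0904 with an estimated correlation). Both guard cell genes were lower in leaf 8, with a median of -1.67 and 2 adjusted over the list alone.

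The other lists did not pass as lists in this contrast. Called higher in leaf 8 were 1 of 5 jasmonate turnover genes (camera adjusted p = 0.339), 1 of 3 defence outputs, whose median was -0.15 though camera ranked the list upwards (camera adjusted p = 0.696), 1 of 8 touch and calcium genes (camera adjusted p = 0.339) and 3 of 8 electrical signalling candidates (camera adjusted p = 0.133). Of the 3 photosynthesis genes 1 was lower (camera adjusted p = 0.405), and these 5 counts were the same adjusted over the list alone. Limma called 0 of 3 signalling, 0 of 4 auxin and 0 of 3 heat shock genes, with 0, 0 and 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.696, 0.574 and 0.558). OPCL1, BCAT4, EIN3, GI, SWEET11 and WRKY53 were higher, each the 1 called gene of its untested list and 1 adjusted over that list alone, and TRY was not called, with 0 at an unadjusted p under 0.05.

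In all, 4391 genes passed in limma between the control leaves, 2223 higher and 2168 lower in leaf 8. With median centring, which moved the median of all genes from -0.02 to -0.12, the split was 1693 higher and 3153 lower. The arrays did not overlap for 45.4% of genes, where chance gives 10%. RNA measures moved with the experiment: the actin probes at the 3' end exceeded those at the 5' end by 2.37 and 2.41 in leaf 8 without and with current, against 1.60 and 1.53 in leaf 13 without and with wounding. The 25S ribosomal RNA probe sets were at 11.11 and 11.09 against 9.92 and 9.88 in the same order. Leaf position, the wire and the experiment cannot be told apart here.

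**Figure D3:**
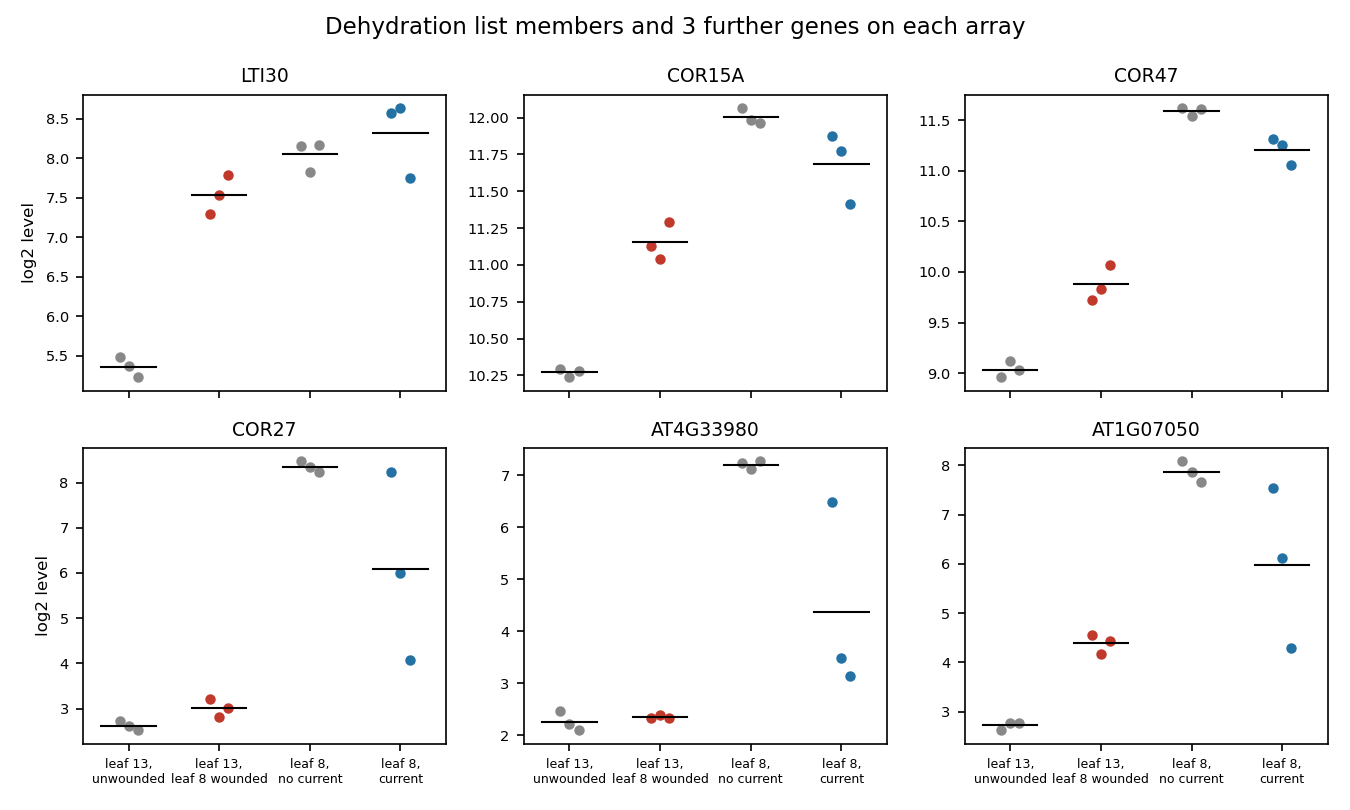
Each point is the log2 RMA level of 1 gene on 1 array in the 4 groups of 3 arrays, for 3 dehydration list members and 3 genes with a large difference between the control leaves, and black lines are group means. COR27 lay at 8.23, 5.99 and 4.07 on the current arrays, while its no-current mean was 8.35.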

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

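The tests of baseline, signal compression and array noise in this part were chosen after the results were seen, while the regroupings of arrays were set before.

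The response to current differed from the response to distal wounding for 381 genes by limma's test of the difference. The genes with the most positive difference, current minus wounding, were AT5G12050 (2.3), AT5G47610 (2.26), IAA29 (2.11), AT5G07580 (2.05) and AT4G37080 (1.78). Those with the most negative difference were AT1G07050 (-3.55), AT4G36010 (-3.46), AT4G17470 (-3.08), AT2G38240 (-3.0) and AT5G05600 (-2.93). When the arrays were relabelled within each experiment, 8 of 100 draws, the real one included, gave as many genes, and the highest other draw gave 2087, so this count does not exclude chance. The highest draw kept all groups whole and only exchanged the current and no-current labels, so that its contrast added the wound and current responses. All 7 draws that reached the count, besides the real one, were among the 8 other draws that left both wound groups whole and relabelled the current arrays. The highest count among draws that broke up the wound groups was 1. Draws with whole wound groups still hold the whole wound response, so that relabelling says little of the difference itself. The count fell to 253, 247, 249, 227 and 241 without unwounded replicate 1 or 2, wounded replicate 2 or 3, or no-current replicate 3.

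Genes that rose after current rose less than after distal wounding. Over the 114 genes at least 2-fold higher after current, the median change was 1.47, against 2.73 after wounding, and the no-current leaves lay 0.36 above the unwounded ones. For these 114 genes, the level reached was compared as a check for a raised baseline in the wired leaves as the whole cause. That level was lower after current by a median of -0.75, in 88 of 114 genes. Array medians were 6.35, 7.10 and 6.50 after current, against 7.25, 7.54 and 7.73 after wounding. The lower level cannot decide on the baseline, because it sets different leaf positions and experiments against each other, and either may shift levels. A raised baseline therefore stays open. Choosing genes by their rise over the wired leaves passed over those already high there, and for these the baseline was not tested. Compressed signal on the leaf 8 arrays stays open, because RMA equalises the distributions of the arrays and so sets the ratio of their SDs over probe sets, 1.00 for current over wounded arrays. A weaker stimulus, the leaf position and the experiment were not separated by the design, and any of them may contribute.

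AT4G33980, COR27 and AT1G07050 spread widely among the current arrays, with SDs of 1.84, 2.08 and 1.63, against 0.08, 0.11 and 0.21 without current. Noisier current arrays as a whole are argued against by the median SD over genes, which was 1.08 times that of the no-current arrays. A different harvest time or temperature of the current plants could give such a spread. The clock list has only 1 measured member, GI, at 8.16, 7.75 and 7.52 on the current arrays. The 3 genes fell in the same order of arrays as GI. AT4G33980 was at 6.48, 3.48 and 3.15, COR27 at 8.23, 5.99 and 4.07, and AT1G07050 at 7.54, 6.11 and 4.30. That shared order goes with this explanation, but 1 clock gene cannot decide it, so that it stays open. No biological explanation was tested.

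Of the 8730 probe sets that the probe-gene table does not name, and that no comparison of genes used, 787 were higher and 931 lower after distal wounding, and 394 higher and 205 lower after current, in limma with adjustment over all probe sets. The largest rise was 7.47 after wounding, by a probe set that rose by 5.31 after current, and the next was 7.16, with 4.70 after current. The largest fall after wounding was -3.75, with -0.98 after current, and the next was -3.47, in a probe set at -1.24 after current that did not pass there (limma adjusted p = 0.225).

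Other splits of the arrays were set beside each count. The 6 arrays of 1 comparison make 10 splits, too few for a share under 0.05. For distal wounding the real split gave 1900 genes and the highest other 0, for current 529 and 5, and for the control leaves 4391 and 0. The current count fell to 266, 338 and 329 without current replicate 2, no-current replicate 1 or no-current replicate 3. For the same-direction overlap of 401 genes, 1 of 100 relabelled draws, the real one, reached that count and the highest other gave 1. This speaks against chance only for the joint grouping of both comparisons, while for either alone the splits are too few. It follows largely from the splits of each comparison, where other splits called at most 0 genes for wounding and 5 for current. It is therefore not separate evidence. Draws that break up a comparison call few genes in it, so they do not test whether the responses share more genes than independent lists of their sizes, for which 18.5 higher and 17.8 lower genes are expected. That overlap fell to 261 without no-current replicate 3 and to 219 without current replicate 2. For the 7 list tests passed over both responses, 5 of 100 draws reached as many and the highest other gave 8, so chance cannot be excluded by this count. The other 4 draws had left the wound groups whole. Among them was the draw that only exchanged the current and no-current labels, which repeats the real tests with the current direction turned. Of the 91 draws that broke up the wound groups 23 passed 4 or more list tests, and the highest of these passed 6. Such draws still divided the wounded arrays unevenly, so that part of the wound response stayed in their contrasts. Their passes therefore do not measure what chance alone gives.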

How the results depend on the processing

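Families and plastid-encoded genes were tested after the data were seen; the other alternatives were set before. Under the alternatives other than thresholds and left-out arrays, 11 of the 77 results on called named genes lost their call, 10 lost it without some 1 array, 63 kept it in all of these, and 0 turned direction. Single-gene results kept direction and side of the threshold in 2203 settings, and were weaker in 74, stronger in 24 and reversed in 34, with 7 values without a test moved; list and family tests did so in 765, 35, 15 and 11. Changes with stricter thresholds and with all probe sets come from the construction of the setting; for the rest, left-out arrays included, the cause was not tested. With an adjusted p under 0.01, wounding gave 1221 genes (638 lower), current 244 (182 higher, 62 lower), the difference 152 (60 and 92) and the overlap 199. With at least 2-fold change, wounding gave 525 (336 and 189), current 135 (114 and 21), the difference 205 (76 and 129), the control leaves 682 (387 and 295) and the overlap 116. With every probe set, wounding gave 3704 (1597 and 2107), current 1183 (738 and 445), the difference 848 (389 and 459), the control leaves 8427 (4263 and 4164), the overlap 917 and the correlation 0.76. Fitted alone, current gave 291 (210 and 81), and with array weights 331 lower. Leaving out the dimmest 50% of genes gave a correlation of 0.76. With median centring wounding gave 859 higher and 887 lower genes, against 776 and 1124. List tests passed numbered 7, and 3 with an estimated correlation, against 6 to 9 in the other settings. All reversals concern results that did not pass. With array weights MYC4 was at -0.036, LHCB4.1 at -0.0028 and AT1G22690 at 0.037 after current. With median centring, EIN3, FMA and SAG29 were at 0.0045, 0.00046 and 0.021 after current, and with quantile normalization SAG29 was at 0.0096 after current and EIN3 at -0.017 after wounding. The photosynthesis list pointed lower with fry after wounding (adjusted p = 0.781, with 0.787 to 0.981 in camera without 1 array). Fry sets a list against no change and camera against the other genes, so these directions answer different questions. The electrical signalling list turned direction without dim genes after current (camera adjusted p = 0.963). Without 1 array in turn, ranges after current were -0.18 to 0.16 for AT1G22690, -0.43 to 0.12 for AT5G48570, -0.10 to 0.053 for EIN3, -0.11 to 0.10 for FMA, -0.0072 to 0.044 for LHCB4.1, -0.22 to 0.24 for MYC4, -0.13 to 0.13 for SAG29 and -0.0045 to 0.23 for WRKY6. After wounding they were -0.062 to 0.27 for BCAT4, -0.015 to 0.10 for EIN3, -0.039 to 0.15 for GI, -1.69 to 0.22 for PDF1.2, -1.67 to 0.063 for PDF1.2b and -0.035 to 0.24 for SAG29. Camera adjusted p ranged from 0.293 to 0.997 for auxin in the difference, 0.451 to 0.962 for electrical signalling after current, 0.191 to 0.972 for defence outputs between the control leaves and 0.251 to 0.813 after wounding. Current gave 266 to 728 genes (187 to 404 higher, 79 to 324 lower), the difference 227 to 469 (96 to 226 and 123 to 266), the overlap 219 to 473 and the correlation 0.63 to 0.75, while wounding stayed at 1405 to 1892. Current gave 266, 338 and 329 genes without current replicate 2, no-current replicate 1 or no-current replicate 3, and 324 lower without current replicate 1. The difference gave 253, 247, 249, 227 and 241 without unwounded replicate 1 or 2, wounded replicate 2 or 3, or no-current replicate 3, and the overlap 261 and 219 without no-current replicate 3 or current replicate 2. Without wounded replicate 1, AT1G53540 passed after wounding (limma adjusted p = 0.0287), and without wounded replicate 3, GH3.3 did (0.0385); WES1 passed after wounding when fitted alone (0.00281), and the rapid stress list after current when fitted alone (camera adjusted p = 0.0338). With fry the jasmonate signalling list did not pass after current (adjusted p = 0.0849), and the electrical signalling and photosynthesis lists passed between the control leaves (adjusted p = 0.00598 and 0.00214). Signal over background limits genes near the lower end of the scale.

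With the replicate number as a block, wounding gave 1771 genes (750 higher, 1021 lower), current 547 (326 and 221), the difference 394 (174 and 220), the overlap 430 and the correlation 0.71, with 8 list tests passed. Under the block GI, GLR3.3, TRY and COR15B passed after current (limma adjusted p = 0.00767, 0.0447, 0.0310 and 0.0305), as did the dehydration list (camera adjusted p = 0.0485). After wounding WRKY6 passed (limma adjusted p = 0.0473), and GLR3.5 and SWEET11 did not (0.0608 and 0.118). The numbers do not pair the arrays: deviations of same-numbered arrays correlated from -0.07 to 0.04, and 1 of 6 arrays correlated best with its own number.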

Other observations

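The gene families below, the plastid-encoded genes and the tests of them were chosen after the data were seen, among 38 families and sets tested together, while the test of neighbouring genes was set before.

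Genes with a symbol outside the fixed lists, picked here after their values were seen, added further groups. The glucosinolate transporters GTR1 and GTR2 rose by 2.72 (SE 0.21) and 1.39 (SE 0.14) after distal wounding and by 1.98 and 0.96 after current, all past the threshold in limma. The expansin genes EXPA8 and EXPB1 fell by 2.44 (SE 0.33) and 1.2 (SE 0.19) after wounding, while EXPA16 rose by 1.36 (SE 0.15). Of the 10 measured EXPA genes, EXPA8 was the 1 called lower and EXPA16 the 1 called higher, 8 were not called, and the family did not pass (camera adjusted p = 0.985). Of 14 measured SWEET sugar transporter genes 2, SWEET16 and SWEET4, rose by 2.06 and 1.13, and 3 fell, SWEET2 by 1.42, SWEET13 by 0.92 and SWEET11, which is in the fixed vascular list. The other 9 were not called, and that family did not pass either (camera adjusted p = 0.985). For EXPA16, SWEET2, SWEET4, SWEET13 and SWEET16 the response to current differed from that to wounding (limma adjusted p = 0.00635, 0.00147, 0.0308, 0.0299 and 0.0397). Of 1557 symbol-bearing genes, 116 were higher and 181 lower after wounding, and 51 higher and 29 lower after current.

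Among families, 4 of 8 autophagy genes (ATG) fell after wounding, with ATG8E at -1.45 (SE 0.16) and ATG8F at -0.60 (SE 0.13), and the family passed (camera adjusted p = 0.00244, but adjusted p = 0.936 with an estimated correlation). After current ATG8E fell by 0.65 (SE 0.16), 1 of 8 (camera adjusted p = 0.0185, but adjusted p = 0.879 with an estimated correlation). Between the control leaves all 8 were higher in leaf 8 (camera adjusted p = 6.85e-05, but adjusted p = 0.249 with an estimated correlation). Of 9 U-box ligase genes (PUB) 3 rose after wounding, PUB43 by 2.95 (SE 0.16), PUB19 by 2.78 (SE 0.41) and PUB24 by 1.29 (SE 0.23), and PUB19 and PUB43 also after current. That family passed for wounding (camera adjusted p = 0.0363, but 0.0536 with median centring and adjusted p = 0.936 with an estimated correlation) and for current (camera adjusted p = 0.00222, but adjusted p = 0.879 with an estimated correlation). The PUB call for wounding ended without unwounded replicate 3 or wounded replicate 2 (camera adjusted p = 0.0718 and 0.184), and the ATG call for current without no-current replicate 2 or current replicate 1 (camera adjusted p = 0.0747 and 0.350). The ATG call for current also ended with array weights or without the dimmest 25% or 50% of genes (camera adjusted p = 0.0505, 0.0618 and 0.0849), and with fry both ATG and PUB missed the threshold for current (adjusted p = 0.0925 for each). Of 15 genes with the stem TRM, which include TRM82, a different protein, 7 fell after wounding, TRM26 and TRM19 at -1.07 (SE 0.18) and -1.05 (SE 0.19) (camera adjusted p = 9.46e-04, but adjusted p = 0.936 with an estimated correlation). Without the dimmest 50% of genes the wound calls of ATG, PUB and TRM ended (camera adjusted p = 0.0630, 0.0630 and 0.193).

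Plastid-encoded transcripts lay lower in leaf 13 after wounding of leaf 8, with a median of -0.31 over 69 genes, 17 of them called, and array medians of 8.39, 8.41 and 7.88 against 8.69, 8.79 and 8.63 (camera adjusted p = 7.85e-05, but adjusted p = 0.986 with an estimated correlation and 0.194 with fry). As a check for less carry-over of RNA without a poly(A) tail, 25S ribosomal RNA differed by -0.042 (SE 0.07). That cannot decide on carry-over, because 25S and plastid levels did not move together on these arrays. From unwounded leaf 13 to leaf 8 without current, 25S went from 9.92 to 11.11 and the plastid median from 8.71 to 8.80. A single array is argued against by the median, which was -0.20 without wounded replicate 3, the nearest to 0 without 1 array. Under quantile normalization and median centring the plastid median was -0.26 at the nearest to 0. That cannot decide on scaling of the arrays, because RMA had already equalised them. The median wound change of all genes moved only from -0.034 to -0.032 and 0.011 under these scalings. A response of plastid transcripts may remain as a hypothesis, but the loss of the call with an estimated correlation, with 3 arrays a group, leaves it unsettled. After current the median was 0.13, with 1 of 69 genes called, higher (camera adjusted p = 1.49e-04, but adjusted p = 0.951 with an estimated correlation and 0.703 with fry), and that call ended without no-current replicate 3 or current replicate 3 (camera adjusted p = 0.574 and 0.196). Its median was 0.23, 0.20 and 0.047 without no-current replicate 1, 2 or 3, and 0.25 and 0.038 without current replicate 1 or 3.

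A hypothesis set before its test was that neighbouring genes on a chromosome share part of their response. Over 5198 adjacent pairs of 8318 genes, the wound responses of neighbours correlated with Spearman rho = 0.13, and the current responses with 0.11, across genes, which are not independent replicates. The highest of 10000 shuffled gene orders gave 0.0473 for wounding, and the one-sided permutation p of 1e-04 is the smallest they can give. This is consistent with a shared response of neighbours, but tandem duplicates with similar regulation or shared hybridisation could give the same and were not separated.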
